A study of Mus musculus with 9 samples.

How the data were processed

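The series holds 9 RNA-seq libraries of mouse spleen B cells that the labels call pre-GC, meaning a stage before the germinal centre, where B cells divide and mutate their antibody genes. 4 libraries carry the label WT and 5 the label p52Ki, with titles that read p52ki/ki, the notation for a knock-in on both alleles, of p52, the DNA-binding protein made from the Nfkb2 gene. The design text also speaks of germinal centre B cells, which were not analysed here. How the knock-in was made, whether the mice were immunised and how the cells were sorted are not given in the sources used here. The labels do not say that libraries of a genotype came from separate mice, so p-values measure the spread between these samples, which may be partly technical.

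Per the labels' protocols, RNA was isolated with a low-input column kit, and cDNA was made with the SMART-Seq v2 method, which amplifies full-length cDNA by PCR, and cut into paired-end libraries with the Nextera XT kit. This method does not mark the strand of the RNA, and reads carry no molecular identifiers, so duplicated reads are not independent molecules. Per the submitters' processing notes, HISAT2 2.1.0, SAMtools 1.8 and featureCounts of Subread 1.6.2 were used with the mouse genome build GRCm38. The annotation release, the strand setting and any read filter are not given in the sources used here. The authors deposited raw counts per gene for 55536 genes, with no normalization. They also deposited log2 CPM values, the logarithm of counts scaled to library size, for 12849 genes. Those deposited log2 values equalled the log CPM that edgeR gives from the deposited counts with TMM factors and a prior count of 2, with a largest difference of 4.97e-14, over the same 12849 genes that the filter below keeps.

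Differences between p52Ki and WT were tested on the deposited counts in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults, libraries were scaled by TMM, and a robust quasi-likelihood F test with no covariate was fitted to all 9 libraries. P-values are two-sided and were adjusted by Benjamini-Hochberg over the 12849 genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were taken as the fold change over the square root of F. Levels are CPM on TMM-scaled library sizes, given as mean ± SD. Where a genotype had 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the genotype's summed libraries (0.102 CPM in WT, 0.100 CPM in p52Ki). Where it had 1 to 3 counts, the ratio has an exact 95% binomial interval. Both cover counting error only.

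33 gene lists were fixed before the data were examined. They comprised B cell programmes, signalling and metabolic pathways, signs of RNA handling and markers of other spleen cells. The 30 lists with at least 3 genes tested were tested with camera of limma 3.58.1 on log2 CPM at a preset correlation between genes of 0.01, adjusted over the 30 lists. Each was tested again with an estimated correlation and with fry. Single measures per library were compared by exact two-sided permutation over the 126 splits of 9 libraries into 4 and 5, whose smallest p is 0.00794. They were adjusted over the 29 measures in that family.

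The genes named were set by a rule made before the data were examined. Some genes were named whatever their result (Nfkb2, Ets1, Bcl6, Fas, S1pr2, Irf4, Prdm1, Myc and Relb). To these were added up to 12 rises and 12 falls of largest log2 fold change among called genes with mean log2 CPM of at least 1 and no overlap between genotypes. Predicted genes, pseudogenes, immunoglobulin and T cell receptor segments, ribosomal and mitochondrial genes were left out of these. Up to 4 members of smallest p were added from each list that was called or held a called gene. A few results that the rule names are not reported here. Genes named outside this rule are said to be chosen after their values were seen. Positions are from GENCODE M21 on GRCm38, in which 55450 of the 55536 identifiers were found, all under the deposited name.

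The test was checked on simulated counts drawn from the means, spread and library sizes of these libraries, with 200 genes changed. Of 12288 genes tested, 27.2% of those changed 2-fold and 56.1% of those changed 4-fold were recovered, and 8.05% of the calls were false. In the real libraries the biological coefficient of variation was 0.567. Total counts were 7937579, 7368604, 7424622 and 7828712 in WT replicates 1 to 4, and 6647650, 5624376, 5976325, 6434492 and 4492160 in p52Ki replicates 1 to 5.

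The alternatives fixed beforehand were DESeq2 size factors, no filter on low counts, a filter of at least 10 CPM in 4 libraries, removal of immunoglobulin and T cell receptor genes, the replicate number as a block, each library left out in turn, DESeq2 1.42.0, limma-voom with quality weights, and limma-trend on the deposited log2 values. A correction for GC content and transcript length was added after seeing the data. GC content was known for 12830 (99.85%) of the genes tested. The pairs of libraries within a genotype differed far beyond counting noise (chi-square per degree of freedom of at least 36.9 in WT and 24.2 in p52Ki). None was therefore treated as a second sequencing of the same library. Libraries made apart from 1 RNA sample would also exceed that noise, as duplicated reads are not independent molecules. The check thus cannot show that the samples are separate.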

Results

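RNA from spleen pre-germinal centre B cells was sequenced in 4 WT and 5 p52Ki libraries. The p52 protein is a subunit of the NF-kB family of transcription factors, and the series title pairs it with ETS1, another transcription factor, in the formation of germinal centres. The comparison asks which transcripts differ between the genotypes in cells labelled as before that stage. Whether the cells precede it was not tested. The WT libraries held the germinal centre B cell genes S1pr2 and Gcsam at 523 ± 102 and 496 ± 103 CPM. Ighg1, of the switched class IgG1, made up 23.1% ± 3.44 of their heavy chain constant counts. Total counts assigned to genes ran from 7368604 to 7937579 in WT and from 4492160 to 6647650 in p52Ki (mean 7639880 ± 285312 against 5835000 ± 849609, SD, n = 4 and 5, exact permutation p = 0.0159, adjusted 0.0460 over 29 measures). Xist, the transcript of the inactive X chromosome, was counted in all 9 libraries, and Ddx3y of the Y chromosome had 0 counts in each.

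Nfkb2, the gene that encodes p52 and its precursor p100 (chromosome 19, 46304320 to 46312385), stood at 145, 175, 129 and 93.8 CPM in WT replicates 1 to 4 and at 202, 150, 198, 228 and 261 CPM in p52Ki replicates 1 to 5. The means were 136 ± 34.0 and 208 ± 40.9 CPM (SD, n = 4 and 5), a log2 fold change of 0.61 ± 0.21 (SE) that did not pass the threshold (edgeR adjusted p = 0.0987). DESeq2 called it, with an adjusted p of 0.0306. Ets1 (chromosome 9, 32636221 to 32757820) was abundant in both genotypes, at 898 ± 85.4 CPM in WT and 1179 ± 294 CPM in p52Ki, and its log2 fold change of 0.39 ± 0.18 did not pass (edgeR adjusted p = 0.232). p52Ki replicates 1 to 4, at 1544, 1116, 1358 and 1111 CPM, lay above every WT library (up to 1004 CPM). p52Ki replicate 5, at 765 CPM, lay below them all. Without that library the log2 fold change of Ets1 was 0.54 and still did not pass (edgeR adjusted p = 0.0519). Counts per gene do not separate transcripts of a modified allele from others. Psd and AC114539.1 overlap Nfkb2 on the other strand, and reads within the overlap cannot be told apart by strand. How many reads of Nfkb2 this affects was not measured.

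Of 17 NF-kB subunits and alternative pathway components tested, 2 rose and 0 fell (5 rose adjusted over the list alone). Cd40, a receptor that activates B cells, rose from 92.0 ± 14.5 to 191 ± 20.7 CPM (log2 fold change 1.05 ± 0.16, edgeR adjusted p = 0.00387). Rel, the c-Rel subunit, rose from 153 ± 28.5 to 316 ± 83.8 CPM (1.04 ± 0.22, edgeR adjusted p = 0.0154). Relb, the usual partner of p52, was at 62.5 ± 17.5 and 63.0 ± 24.8 CPM (edgeR adjusted p = 0.989), and Ikbkb and Birc3 had log2 fold changes of 0.56 and 0.54 without passing (edgeR adjusted p = 0.0638 and 0.0947). The list did not pass (camera adjusted p = 0.0720, and adjusted p = 0.194 with an estimated correlation), though it did at 10 CPM in 4 libraries (0.0244), on voom values (0.0157), with fry (0.00203) and without p52Ki replicate 5 (0.0482). Among 19 NF-kB target genes, Nfkbia and Nfkbie, inhibitors of NF-kB, rose by 0.94 ± 0.15 and 0.71 ± 0.19 in log2, while Cd83, an activation marker, and Stat5a changed by -0.70 ± 0.14 and -1.15 ± 0.24 (camera adjusted p of the list 0.572). The call of Nfkbie ended in 6 of the 9 fits without 1 library, those without WT replicates 1, 3 and 4 and p52Ki replicates 1, 2 and 3, at adjusted p up to 0.0978, and after the GC and length correction (0.0632).

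Of 15 ETS family genes, 2 rose and 0 fell. Spib, a B cell ETS factor, rose from 970 ± 148 to 1510 ± 236 CPM (0.64 ± 0.15, edgeR adjusted p = 0.0230), and Elk4 from 41.4 ± 8.16 to 73.2 ± 8.02 CPM (0.82 ± 0.21, edgeR adjusted p = 0.0316). Elf4 had a log2 fold change of 0.42 ± 0.20 and did not pass (edgeR adjusted p = 0.255). The list was not called (camera adjusted p = 0.458). The call of Spib ended without WT replicate 3 or 4 or p52Ki replicate 1 or 3, and that of Elk4 without WT replicate 1 or 3 or p52Ki replicate 1, 2, 3 or 5, at adjusted p up to 0.0600 and 0.0767.

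Lists of germinal centre, S phase and G2 and M phase genes were lower in p52Ki, and that of resting follicular B cells was higher, at a preset correlation between genes but not at an estimated one (adjusted p = 0.193, 0.194, 0.199 and 0.193). Immediate early genes were also higher and heat shock genes lower, again not with an estimated correlation (camera adjusted p = 0.194 for both). The mean of 2 stromal markers was higher. Gcsam, a regulator of B cell motility (chromosome 16, 45610380 to 45622867), fell from 496 ± 103 to 112 ± 58.1 CPM (SD, n = 4 and 5), a log2 fold change of -2.14 ± 0.32. Ccr7, a chemokine receptor that draws B cells to the T cell zone (chromosome 11, 99144196 to 99155077), rose from 70.0 ± 18.7 to 531 ± 102 CPM, a log2 fold change of 2.92 ± 0.23. Both passed (edgeR adjusted p = 0.00351 and 0.000313), with every p52Ki library on one side of every WT library.

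Of 12849 genes tested, 1096 (8.53%) passed the threshold, 577 higher and 519 lower in p52Ki (52.6% higher), and 728 of them changed by over 2-fold. The genotypes did not overlap in 1777 of the 12849 genes, where chance gives such separation for 1.59%. After correction for GC content and length, an alternative added after seeing the data, 1296 genes passed, 489 higher and 807 lower (37.7% higher). DESeq2 called 2042 genes. The count was 714 without WT replicate 1, 711 without WT replicate 4, and 651, 625 and 716 without p52Ki replicates 1, 3 and 5. The first principal component, with 41.0% of the variance, separated the genotypes (mean scores -35.5 ± 13.1 and 28.4 ± 6.95, exact permutation p = 0.00794, the smallest possible with n = 4 and 5), and the second did not (exact p = 0.770).

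**Figure D1:**
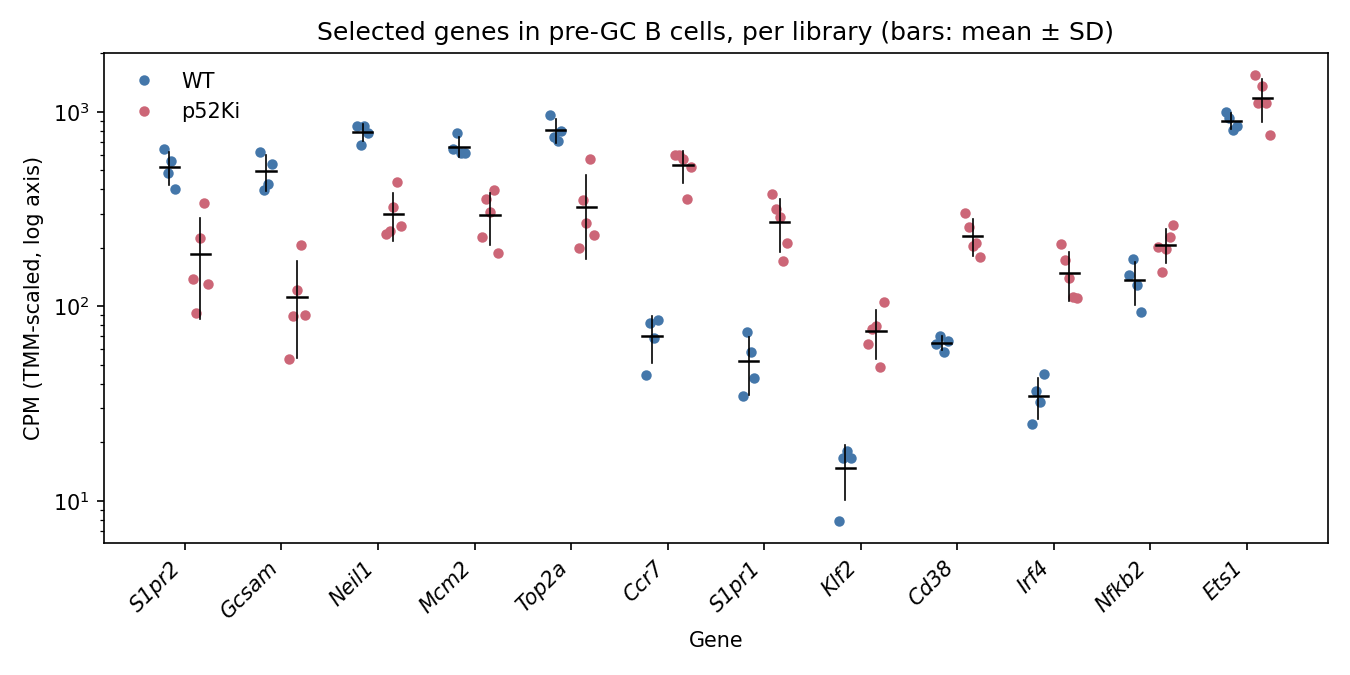
CPM on TMM-scaled library sizes (log axis) of selected genes, with 1 point per library in 4 WT and 5 p52Ki libraries and bars for the mean and SD. S1pr2, Gcsam, Neil1, Mcm2 and Top2a lie lower in p52Ki, Ccr7, S1pr1, Klf2, Cd38 and Irf4 lie higher, and Nfkb2 and Ets1 overlap between the genotypes.

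All 22 germinal centre B cell genes were measured, of which 12 fell and 0 rose (15 fell adjusted over the list alone), with a median log2 fold change of -1.15. Beside Gcsam, Rassf6 fell by 2.05 on the log2 scale and Neil1, a DNA repair glycosylase, fell by 1.40 (edgeR adjusted p = 0.00346 and 0.00218). S1pr2, a receptor that holds B cells in the germinal centre, fell from 523 ± 102 to 185 ± 99.8 CPM, and Fas, the death receptor, from 197 ± 26.4 to 81.2 ± 29.3 CPM (edgeR adjusted p = 0.0169 and 0.0111). Bcl6, the repressor that directs the programme, was at 63.6 ± 14.2 and 38.6 ± 9.45 CPM and did not pass (-0.72 ± 0.26, edgeR adjusted p = 0.113). The list was called (camera adjusted p = 1.5e-11), though not with an estimated correlation (adjusted p = 0.193).

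Of the 24 S phase genes, 18 fell and 0 rose, with a median log2 fold change of -0.96, and of the 24 G2 and M phase genes 18 fell and 0 rose, with a median of -1.28. Mcm2, Mcm5 and Mcm7, parts of the replicative helicase, changed by -1.17 ± 0.21, -1.23 ± 0.22 and -1.0 ± 0.19, and Slbp, which binds histone mRNA, by -0.91 ± 0.15. Top2a, a topoisomerase of dividing cells, fell from 803 ± 113 to 326 ± 151 CPM, and the mitotic genes Ccnb2, Tpx2 and Aurka changed by -1.28 ± 0.24, -1.23 ± 0.23 and -1.27 ± 0.26. Both lists were called (camera adjusted p = 1.1e-12 and 2.4e-14), but not with an estimated correlation (adjusted p = 0.194 and 0.199). Without WT replicate 1, 3 or 4 or p52Ki replicate 1, 3 or 5, 9, 10, 10, 11, 9 and 10 S phase genes were called, and without WT replicate 1 or 4 or p52Ki replicate 3 or 5, 10, 9, 8 and 11 G2 and M phase genes were called. None of 22 MYC and ribosome biogenesis genes passed (edgeR, camera adjusted p of the list 0.519), and Myc was at 113 ± 9.0 and 157 ± 51.5 CPM (edgeR adjusted p = 0.248).

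Of 18 resting follicular B cell genes, 12 rose and 0 fell, with a median log2 fold change of 1.41. S1pr1, the receptor for exit from lymphoid tissue, rose from 52.4 ± 17.5 to 273 ± 82.1 CPM, and Klf2, the factor that drives its expression, from 14.8 ± 4.66 to 74.8 ± 21.1 CPM. Cd38, a surface enzyme low on mouse germinal centre B cells, rose from 64.8 ± 5.19 to 231 ± 48.9 CPM (edgeR adjusted p = 0.000816). The list was called (camera adjusted p = 6.4e-07), but not with an estimated correlation (adjusted p = 0.193). Among 20 B cell migration and adhesion genes 8 rose and 3 fell, though 4, 3 and 5 rose without WT replicates 1, 3 and 4 and 3, 4 and 5 without p52Ki replicates 1, 3 and 5. With a library other than WT replicate 4 left out, 2 fell. Itga4, an integrin chain, changed by 1.51 ± 0.21 and Gna13, a G protein that confines germinal centre B cells, by -0.84 ± 0.12 (edgeR adjusted p = 0.00266 and 0.00319). That list did not pass (camera adjusted p = 0.0792), though it did at 10 CPM in 4 libraries (0.0291), on voom values (0.0475) and with fry (0.000891), and not with an estimated correlation (adjusted p = 0.194).

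**Figure D2:**
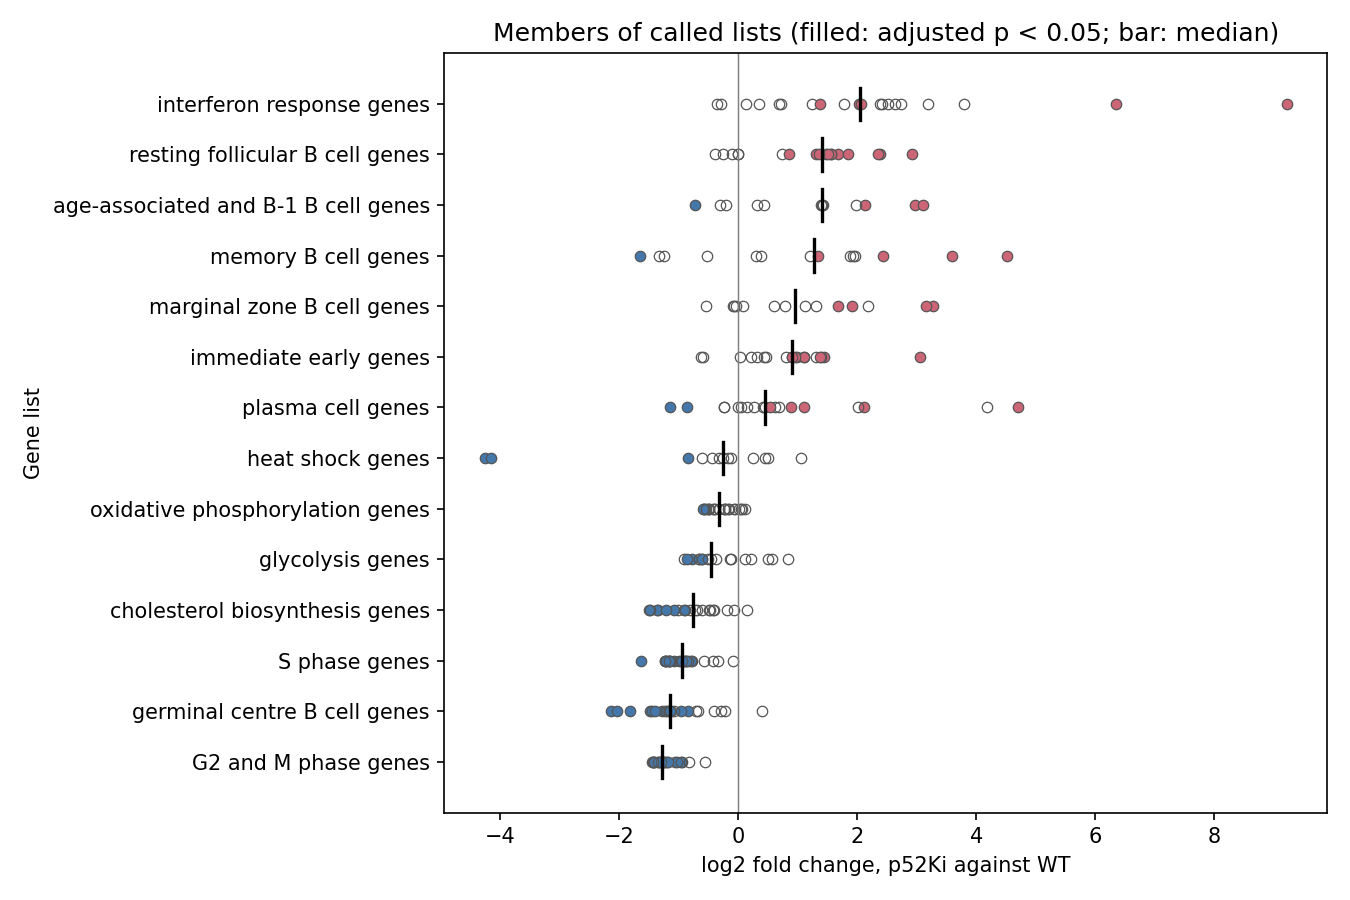
Fitted log2 fold changes (p52Ki against WT) of the members of the 14 lists called by camera, with 1 point per gene, filled where the edgeR adjusted p was under 0.05, and a bar at each median. The medians run from -1.28 for G2 and M phase genes to 2.04 for interferon response genes, whose point farthest right is Ifit1, a gene with 0 counts in WT.

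Of 14 marginal zone B cell genes 4 rose, among them Notch2, the receptor needed for that lineage, from 17.9 ± 5.54 to 67.5 ± 20.6 CPM, Cd36 and Plac8 (camera adjusted p = 0.0190, and adjusted p = 0.268 with an estimated correlation). Of 12 age-associated and B-1 B cell genes 3 rose and 1 fell, Apoe, whose call was kept only without p52Ki replicate 4 (adjusted p up to 0.109 elsewhere), and 2 rose without WT replicate 3 or 4 or p52Ki replicate 2, 3 or 4. Bhlhe41, a repressor used by B-1 cells, changed by 3.11 ± 0.30 and Zeb2, a factor of age-associated B cells, by 2.97 ± 0.38 (camera adjusted p = 0.0190, and adjusted p = 0.193 with an estimated correlation). Of 14 memory B cell genes 4 rose and 1 fell. Hhex, a factor of memory B cells, changed by 3.58 ± 0.60, Bcl2, a survival gene, by 2.43 ± 0.51, and Nt5e by -1.65 ± 0.35. The memory list was called (camera adjusted p = 0.0387, and adjusted p = 0.216 with an estimated correlation), and its call ended without WT replicate 3 or 4 or p52Ki replicate 2 or 4, at adjusted p up to 0.0766. Without WT replicate 4 or p52Ki replicate 2, 2 memory genes rose.

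Irf4, a factor of both activated B cells and plasma cells (chromosome 13, 30749226 to 30766976), rose from 34.6 ± 8.37 to 149 ± 42.5 CPM (2.11 ± 0.26, edgeR adjusted p = 0.00172), while Prdm1, the plasma cell regulator, was at 7.40 ± 4.67 and 8.18 ± 6.78 CPM (edgeR adjusted p = 0.963). Of 19 plasma cell genes 5 rose and 2 fell. Pdia4 and Sec11c, of protein folding and secretion, changed by 1.10 ± 0.19 and 0.88 ± 0.17, and Jchain, the joining chain of IgM and IgA, fell from 1252 ± 194 to 562 ± 202 CPM. The list was called (camera adjusted p = 0.0254, and adjusted p = 0.268 with an estimated correlation). Its call ended without WT replicate 3, p52Ki replicate 1 or p52Ki replicate 2, at adjusted p up to 0.118, and 3 of its genes rose without WT replicate 1, 3 or 4 or p52Ki replicate 1, 2 or 3. Only 1 fell without WT replicate 3 or 4 or p52Ki replicate 3 or 5. Of 16 unfolded protein response genes 4 rose, among them Hsp90b1 and Dnajb9, with log2 fold changes of 1.06 ± 0.16 and 1.30 ± 0.25, and the list did not pass (camera adjusted p = 0.136), though it did at 10 CPM in 4 libraries (0.04997), on voom values (0.0463) and with fry (0.0282), and not with an estimated correlation (adjusted p = 0.525).

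Of 20 cholesterol biosynthesis genes 6 fell and 0 rose, with a median log2 fold change of -0.77. Sqle, the squalene epoxidase, fell from 124 ± 16.5 to 48.0 ± 15.8 CPM, and Msmo1 from 105 ± 29.6 to 45.2 ± 11.2 CPM (camera adjusted p of the list 9.7e-06, and adjusted p = 0.194 with an estimated correlation). Without WT replicate 1 only 2 of them were called, and 3 without p52Ki replicate 2, 3 or 5. Of 17 glycolysis genes 4 fell, led by Tpi1 and Pgam1 at -0.78 ± 0.16 and -0.86 ± 0.19 (camera adjusted p = 0.00507, and adjusted p = 0.2998 with an estimated correlation). Without WT replicate 1 only 1 glycolysis gene was called, as Pgam1, Pkm and Eno1 lost their calls (adjusted p = 0.0510, 0.0561 and 0.120), and 2 were called without WT replicate 3 or 4 or p52Ki replicate 1, 3 or 5. Of 23 oxidative phosphorylation genes 3 fell, among them Atp5a1 of ATP synthase, at -0.60 ± 0.14 (camera adjusted p = 0.000874, and adjusted p = 0.266 with an estimated correlation). Of the 3 calls, of Atp5a1, Sdha and Ndufs1, 0 remained without WT replicate 1 or p52Ki replicate 3, 3 without p52Ki replicate 4 and 1 without any other library (adjusted p up to 0.0667, 0.111 and 0.117).

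Of 20 interferon response genes tested 5 rose and 0 fell (10 rose adjusted over the list alone), with a median log2 fold change of 2.04. Ifit1, which binds viral RNA, had 0 counts in the 4 WT libraries and 11.4 ± 9.94 CPM in p52Ki, at least 111-fold higher, and Mx1, a GTPase against viruses, had 8 counts in WT, all in replicate 2, and 718 in p52Ki. Oasl1 rose from 11 ± 5.63 to 45.3 ± 5.33 CPM and Bst2, or tetherin, from 8.92 ± 5.01 to 37.1 ± 8.17 CPM. The list was called (camera adjusted p = 1.5e-08), but not with an estimated correlation (adjusted p = 0.143). These genes stood at low counts in WT, whose libraries also detected fewer genes.

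Immediate early genes respond within minutes to stimulation or tissue handling. Of 19 tested 8 rose and 0 fell. Ier2 changed by 1.36 ± 0.16, Fosb by 1.44 ± 0.22, Jun by 0.99 ± 0.17 and Zfp36 by 0.94 ± 0.14 (camera adjusted p of the list 6.2e-05, and adjusted p = 0.194 with an estimated correlation). Of 13 heat shock genes 3 fell, among them Hspa1a, from 299 ± 229 to 15.5 ± 7.74 CPM, and Hspa1b, from 41.6 ± 30.8 to 2.30 ± 1.30 CPM, with WT means of 188 and 26.6 CPM without WT replicate 4 (camera adjusted p = 0.0167, and adjusted p = 0.194 with an estimated correlation). With a library other than WT replicate 3 or p52Ki replicate 4 left out, only 2 fell. Hspa1a and Hspa1b are near-identical copies whose reads can be shared, and Gm20481 overlaps Hspa1a on the other strand, so their separate values are uncertain.

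Of 21 B cell receptor signalling genes 2 rose, Cd72, a coreceptor, from 527 ± 66.4 to 1084 ± 177 CPM and Cd79a, a receptor signalling chain, from 1569 ± 315 to 2829 ± 419 CPM, and 4 without p52Ki replicate 4. The list did not pass (camera adjusted p = 0.480, and adjusted p = 0.637 with an estimated correlation), though it did with fry (0.0278). Of 17 CD40, IL-4 and IL-21 response genes 3 rose, Il10ra, Junb and Il2rg, by 1.87 ± 0.32, 1.10 ± 0.19 and 0.74 ± 0.15, and Cd86, a costimulatory ligand, changed by -1.04 ± 0.23 (camera adjusted p = 0.505). Cd86 lost its call without WT replicate 3 or p52Ki replicate 3, at adjusted p up to 0.0558. Of 13 MHC class II presentation genes 1 rose, Ifi30, a lysosomal reductase, by 1.08 ± 0.26, and H2-Aa and H2-Eb1 had log2 fold changes of -0.47 and -0.47 that did not pass (camera adjusted p of the list 0.232). Ifi30 lost its call without WT replicate 1, 2 or 4 or p52Ki replicate 1, 3 or 5, at adjusted p up to 0.0682. Of 16 apoptosis and BCL2 family genes Bcl2 rose and Fas fell (camera adjusted p = 0.572).

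The rises of largest fitted fold were genes with 0 counts in WT. Vangl2, a planar polarity protein (chromosome 1, 172000960 to 172028444), was at 15.7 ± 8.75 CPM in p52Ki, at least 154-fold higher than in WT. Snx33, Lef1, Tlr12, Ppm1e and Pdk2 were at least 129, 124, 109, 107 and 102-fold higher (Lef1 at least 60.2-fold without p52Ki replicate 5), and Zfp72, Angel1, Pik3r6 and Peg13 at least 87.9, 82.2, 72.8 and 70.8-fold higher. In all, 66 called genes had 0 counts in WT and 1 had 0 counts in p52Ki. With limma-voom Vangl2, Snx33, Lef1 and Angel1 did not pass (adjusted p = 0.0625, 0.0598, 0.0692 and 0.156). Peg13 lies within Trappc9, which shares its strand, so reads of the pair can be mixed.

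Among the falls, Pdzd3 (chromosome 9, 44247307 to 44251471) had 0 counts in p52Ki against 6.26 ± 1.58 CPM in WT, at least 62.3-fold lower. Serpinf1, a secreted serpin, changed by -3.77 ± 0.74, Cfap74 by -2.61 ± 0.51, Nlrx1, a mitochondrial NOD-like protein, by -2.56 ± 0.44, Lefty1, a TGF-beta family ligand, by -2.24 ± 0.46 and Arhgap8 by -2.20 ± 0.46. Nlrx1, Cfap74 and Arhgap8 overlap other tested genes on the other strand. Xkr5, Lrr1, Tspan5 and Sh3bgrl2 changed by -5.21 ± 1.30, -2.41 ± 0.63, -2.41 ± 0.66 and -2.25 ± 0.62. Their calls were less stable. Xkr5 kept its call only without WT replicate 4 or p52Ki replicate 4, Lrr1 only without p52Ki replicate 1 or 4, Tspan5 only without p52Ki replicate 2 and Sh3bgrl2 only without p52Ki replicate 4, and elsewhere adjusted p reached 0.0692, 0.0840, 0.174 and 0.113.

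Antibody genes differed in class and segment. Of 8 heavy chain constant genes 2 rose and 1 fell. Ighm, the IgM constant region, rose from 9666 ± 705 to 16733 ± 2172 CPM and Ighd, of IgD, from 98.8 ± 29.6 to 273 ± 49.5 CPM. Ighg1, of IgG1 (chromosome 12, 113325240 to 113330523), fell from 3194 ± 422 to 351 ± 325 CPM (215 CPM without p52Ki replicate 3, -3.18 ± 0.54, edgeR adjusted p = 0.00610), while Ighg3, Ighg2b and Ighg2c, chosen after their values were seen, did not pass (log2 fold changes -0.01, 0.80 and 1.2, edgeR adjusted p = 0.989, 0.302 and 0.321). The list did not pass (camera adjusted p = 0.572). The shares below were chosen after the values were seen. Ighg1 made up 23.1% ± 3.44 of heavy chain constant counts in WT and 1.95% ± 1.95 in p52Ki (1.11% without p52Ki replicate 3, SD, n = 4 and 5, exact permutation p = 0.00794, adjusted 0.0106 over 4 shares). The variable segment Ighv1-72 (chromosome 12, 115757984 to 115758461) held 39.4% ± 2.37 of Ighv counts in WT and 6.58% ± 2.85 in p52Ki, and lambda 1 held 50.5% ± 4.28 and 19.4% ± 1.99 of light chain constant counts (both exact permutation p = 0.00794, adjusted 0.0106). The share of lambda 2 and 3 did not differ beyond the spread (13.3% ± 2.97 and 17.4% ± 3.08, exact permutation p = 0.103). That share is no measure of their level, as the kappa counts it is set against also rose. Iglc2, chosen after its values were seen, ran from 352 to 533 CPM in WT and from 704 to 1369 CPM in p52Ki. Iglc3, chosen likewise, ran from 288 to 499 CPM and from 515 to 1035 CPM. Iglc1 itself did not pass (-0.64 ± 0.20, edgeR adjusted p = 0.0783), though it did with DESeq2, with limma-voom, without p52Ki replicate 2 and after GC and length correction (adjusted p from 0.00482 to 0.04998), while Igkc, the kappa constant region, rose by 1.55 ± 0.15 in log2. Near-identical segments can share reads, so single segments are uncertain.

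**Figure D3:**
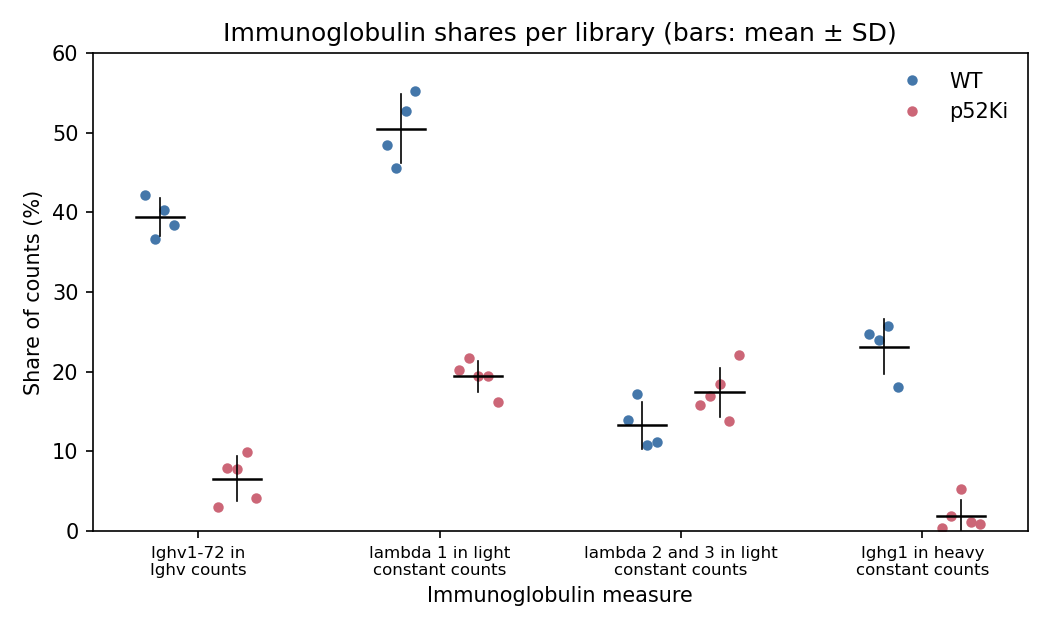
Shares of counts (percent, axis from 0) within heavy chain variable, light chain constant and heavy chain constant genes, with 1 point per library in 4 WT and 5 p52Ki libraries and bars for the mean and SD. Ighv1-72 lies between 36.6% and 42.1% in WT and between 3.05% and 9.93% in p52Ki.

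Outside the macrophage list, few markers of other spleen cells were abundant enough to test. T cell, follicular helper T cell, macrophage, dendritic cell and erythroid lists, with 4 of 18, 3 of 10, 13 of 17, 3 of 13 and 5 of 14 genes tested, were not called (camera adjusted p = 0.569, 0.480, 0.312, 0.819 and 0.972). Neutrophil, natural killer and stromal lists had 0, 1 and 2 genes tested, and the natural killer gene did not pass, at a log2 fold change of 3.48. Among T cell markers Il7r, the IL-7 receptor, had 2 counts in WT, both in replicate 4, and 284 in p52Ki, a ratio of 140 (95% interval 38.3 to 1160), while Lck and Cd247 did not pass (edgeR adjusted p = 0.114 and 0.529). Of dendritic cell markers Bst2 rose and Flt3 changed by -1.44 ± 0.35, a call that ended without WT replicate 2, 3 or 4 or p52Ki replicate 3 or 5, at adjusted p up to 0.0715. The summed level of stromal and follicular dendritic cell markers was 75.9 ± 28.2 CPM in WT and 211 ± 49.6 CPM in p52Ki (exact permutation p = 0.0159, adjusted 0.0460), and their mean log2 CPM 3.59 ± 0.934 and 5.85 ± 0.377 (exact permutation p = 0.00794, adjusted 0.0288). The markers tested were Pecam1, an adhesion protein also made by blood cells, which rose from 71.4 ± 33.2 to 183 ± 54.6 CPM, and Mfge8, at 3.99 ± 4.89 (1.63 without WT replicate 2) and 21.5 ± 12 CPM without passing. The call of Pecam1 ended without WT replicate 2 or 3 or p52Ki replicate 1, 3 or 5, at adjusted p up to 0.0660.

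The p52Ki libraries detected more genes despite lower depth, 15881 ± 448 against 14374 ± 323 in WT. The numbers were 15402 ± 357 against 13891 ± 321 when counts were redrawn with replacement at the lowest total (both exact permutation p = 0.00794, adjusted 0.0288, n = 4 and 5). Immunoglobulin genes took 3.90% ± 0.483 of counts in p52Ki and 2.55% ± 0.239 in WT (exact permutation p = 0.00794, adjusted 0.0288). The shares of mitochondrial genes (2.45% ± 0.289 in WT and 2.17% ± 0.303 in p52Ki) and of ribosomal protein genes did not differ beyond the spread (exact permutation p = 0.238 and 0.913).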

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

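The tests in this part were chosen after the result was seen, except those of other splits of the libraries. Other splits of the 9 libraries do not account for the changed genes: of 100 of the 126 possible splits, 1 gave as many called genes, the real split with 1096, and the highest of the others gave 595. For gene lists 1 of 100 splits gave as many calls, the real one with 14, and the highest of the others gave 13, with 0 genes called. The count of lists cannot exclude chance, as the margin of 1 list is less than the spread of the count. Without 1 library 12 to 15 lists were called, and with an estimated correlation 0 were. The splits with 13 lists and with 595 genes each put 1 p52Ki library with all the WT libraries. Both are thus close to the real split.

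The lower germinal centre and cell cycle genes with higher resting B cell genes could arise from fewer cells of the germinal centre programme in the p52Ki samples or from lower expression within such cells. Dilution by resting cells would lower both kinds of transcript by 1 factor. 6 germinal centre genes (S1pr2, Gcsam, Rgs13, Nuggc, Mybl1 and Rassf6) and the G2 and M phase list differed by -1.60 and -1.31 in mean log2 CPM. The gap between them, -0.290, was within the spread (exact permutation p = 0.310), so these genes cannot tell dilution from altered expression. The shares of Ighv1-72 (39.4% of Ighv counts in WT, 6.58% in p52Ki) and lambda 1 (50.5% and 19.4% of light chain constant counts) also differed. Those shares bear on which B cells were sampled, but do not measure the shares of germinal centre and resting cells. Loss of molecules in the WT libraries that acts by abundance would move genes of like abundance too. Such genes (the 20 outside the lists nearest in level to each member) moved by 0.0573, -0.0536, -0.122 and -0.108 in mean log2 CPM. These values are for the germinal centre, S phase, G2 and M phase and resting lists. The lists moved apart from them by -1.21, -0.956, -1.19 and 1.28 (exact permutation p = 0.00794, 0.0159, 0.0159 and 0.00794). The 4 lists were picked after their shifts were seen, so these gaps largely restate the shifts and do not exclude such loss. They show only that genes of like abundance did not move as far. GC content and length are argued against, as 100% of the 59 called members of the 4 lists kept call and direction after that trend was removed. Signs of handling and stromal markers moved with the pattern: in mean log2 CPM, immediate early genes by 0.945, heat shock genes by -0.687 and the 2 stromal markers by 2.26 (each exact permutation p = 0.00794). Handling, other cells and genotype stay open as sources, untested.

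Genes with 0 counts in WT that rise in p52Ki were 66 of the called genes. Sequencing depth is argued against, since the p52Ki libraries were shallower and detected 1511 more genes at equal depth (exact permutation p = 0.00794). Fewer molecules captured in the WT libraries is consistent with the rest of the table: among 3043 uncalled genes of mean log2 CPM under 3, 20.6% ± 3.34 were at 0 in WT libraries and 8.76% ± 3.0 in p52Ki, a gap of 11.8 points (exact permutation p = 0.00794). A wider mix of cells in p52Ki would give more genes as well and was not tested, so these rises, Vangl2, Lef1 and Ifit1 among them, may be partly technical.

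Single libraries stood far from the others of their genotype in 24 of 305 groups checked (7.87%), where chance gives about 1 in 20 (5%). p52Ki replicate 5 had 23.5 CPM of Ppm1e (others up to 9.73) and 474 CPM of Nfkbia (others up to 423). p52Ki replicate 4 had 1.38 CPM of Xkr5 (others 0), 2267 CPM of Cd79b (others from 2872), 16.2 CPM of Cd247 (others up to 7.55), 321 CPM of Fam129c (others from 590) and 1489 CPM of Ighg2b (others up to 571). p52Ki replicate 2 had 1.94 CPM of Hspa1a (others from 16.4), 5.11 CPM of Tspan5 (others up to 1.99), 349 CPM of Cd36 (others up to 183) and a mitochondrial share of 1.64% (others from 2.18%). p52Ki replicate 3 had 61.2 CPM of Ighv14-3 (others up to 30.3). WT replicate 1 had 24.5 CPM of Tspan5 (others up to 9.13), 7.88 CPM of Klf2 (others from 16.6), 33.7 CPM of Cd36 (others from 68.6) and 73.0 CPM of Ighe (others up to 13.0). WT replicate 2 had 4.15 CPM of Klf3 (others up to 0.266), 778 CPM of Mcm2 (others up to 641), 1.11 CPM of Mx1 (others 0), 0.415 CPM of Slamf9 (others 0) and 499 CPM of Iglc3 (others up to 324). WT replicate 4 had 92.1 CPM of Nt5e (others up to 83.9), 10720 CPM of Ighm (others up to 9433) and 0.266 CPM of Il7r (others 0).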

How the results depend on the processing

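Of 150 named genes, those chosen after seeing included, 120 were called. Call and direction were kept by 37 with the replicate block (83 lost the call), by 95 (without p52Ki replicate 3) to 115 without 1 library in turn, and by 105 to 120 in the other settings, where not all were tested. No planned setting turned the direction of a called named gene. At this depth, number of libraries and spread, 27.2% of simulated 2-fold changes were recovered, and which of these sets the limit was not tested.

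DESeq2, which tested 14986 genes, called 2042 (1229 higher, 813 lower), while limma-voom and limma-trend on the same 12849 genes as edgeR called 1094 and 1401, and the cause was not tested. DESeq2 called Nfkb2 (log2 fold change 0.64, adjusted p = 0.0306, against 0.0568 to 0.310 in the other settings). Without 1 library, and so with fewer samples, edgeR called 625 to 1108 genes (344 to 551 higher, 262 to 557 lower). The correction for GC content and length, chosen after seeing the data, gave 807 lower genes, and the cause was not tested. With an estimated correlation 0 of 14 lists stayed called. The estimate was 0.584 for S phase and 0.741 for G2 and M phase genes, against the preset 0.01. For the age-associated and B-1 list it was -0.0180, below the preset, yet the camera adjusted p went from 0.0190 to 0.193. A higher correlation between genes thus cannot account for every lost call, and what else does was not tested. With fry 18 lists were called. The NF-kB subunit, migration and unfolded protein response lists passed with fry, at 10 CPM in 4 libraries and on voom values, and the B cell receptor signalling list with fry alone. Without 1 library 12 to 15 lists were called.

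With the replicate block, 129 genes were called (97 higher, 32 lower). No pairing by number was seen: same-numbered libraries correlated at -0.042, -0.0172, -0.0131 and -0.00898, and none correlated best with its own number. The best correlations with any number were only 0.0123 to 0.0734, so this check cannot exclude a shared day or batch. The block also leaves fewer degrees of freedom, and p52Ki replicate 5 has no WT library of its number. The block changed no list call (14 of 14) and gave Prdm1 a log2 fold change of -0.33 and the erythroid list an adjusted p of 0.974 in the other direction.

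Results that never passed changed direction, and the cause was not tested. Ighg3 (-0.01) was 0.0139 with DESeq2 size factors, 0.00249 with no filter, 0.0248 at 10 CPM in 4 libraries and 0.0140 with DESeq2. Prdm1 was -1.27 with limma-voom and -0.52 with limma-trend. Relb was -0.0421 with limma-trend and -0.17 after the GC and length correction, which gave Iglv2 (0.36) -0.25. T cell markers turned with fry (adjusted p = 0.599) and erythroid markers on voom values (0.994). Without 1 library in turn Prdm1 ran from -0.31 to 0.57, Relb from -0.20 to 0.21 and Ighg3 from -0.13 to 0.21. The adjusted p of dendritic cell markers ran from 0.647 to 0.995 and that of erythroid markers from 0.560 to 0.999, each with some changes of direction.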

Other observations

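The tests in this part, that of shared reads among V segments included, were chosen after the result was seen. Several genes outside the naming rule, chosen after their values were seen, were higher in p52Ki. Fam129c, a B cell gene, rose from 53.1 ± 18.2 to 571 ± 145 CPM, Ccnd2, a D-type cyclin, from 47.1 ± 10.4 to 261 ± 47.5 CPM and Sdc4, a syndecan, from 66.8 ± 23.3 to 477 ± 148 CPM (SD, n = 4 and 5, edgeR adjusted p = 0.000313, 0.000313 and 0.00109). Slamf9 had 3 counts in WT, all in replicate 2, and 1142 in p52Ki, a ratio of 375 (95% interval 128 to 1820, counting error only).

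Members of the interferon-inducible Ifi200 family, which bind DNA, lie together on chromosome 1 (173350879 to 173942672), and 6 of the 10 tested were called, all higher. Without WT replicate 2 only 3 of 11 were called, and 4 or 5 without any other library. Mndal rose from 43.8 ± 10.2 to 219 ± 86.3 CPM and Ifi206 from 8.95 ± 7.0 to 105 ± 16 CPM. These paralogs overlap or resemble each other, so single members are uncertain. MHC class I heavy chain genes were called in 7 of 13, all higher, with H2-K1 from 1560 ± 135 to 2996 ± 210 CPM and H2-D1 from 1952 ± 106 to 3603 ± 151 CPM, under the same limit of shared reads. Of 92 Igkv segments 34 were called, all higher, and of 89 Ighv segments 17 were higher and 3 lower. Without 1 library in turn 22 to 30 Igkv segments were called, all higher, and 9 to 15 Ighv segments were higher and 2 or 3 lower. Within 5 Mb of Nfkb2, 4 of 82 genes were called (4.88% against 8.55% elsewhere, Fisher's exact p = 0.320). Without 1 library in turn 2 to 6 were called, 6 of 84 without WT replicate 3 (7.14% against 5.78% elsewhere).

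The lower share of Ighv1-72 could come from reads moving to near-identical V segments, which the table argues against: summed with its 5 nearest relatives by shared sequence, Ighv1-72 went from 805 ± 65.0 to 381 ± 162 CPM, a change of -424 CPM (exact permutation p = 0.00794). The 5 relatives alone were at 156 ± 45.1 and 227 ± 94.9 CPM, within the spread (exact permutation p = 0.278). A general drop in antibody transcript would not by itself lower a share within Ighv counts. Nor was such a drop seen, as immunoglobulin genes took 2.55% ± 0.239 of counts in WT and 3.90% ± 0.483 in p52Ki (exact permutation p = 0.00794). Of the Ighv segments 17 were called higher and 3 lower. Whether fewer cells with Ighv1-72 or less transcript within those cells lies behind its lower share was not tested and stays open. The lower share of lambda 1 is no measure of lambda 1 alone, as Igkc went from 2302 ± 383 to 6744 ± 1028 CPM while Iglc1, at 3264 ± 899 and 2089 ± 496 CPM, did not pass (edgeR adjusted p = 0.0783).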
